A study of Brachypodium distachyon with 36 samples.

How the data were processed

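Shoots of four-day-old Brachypodium distachyon Bd21-3 seedlings were measured by paired-end RNA sequencing in 36 libraries, 3 replicates in each of 12 groups. The groups cross 3 genotypes, the wild type (WT) and the mutant lines Bdkai2-1 and Bdkai2-2, with 4 treatments of 4 h: an acetone mock, 1 µM of the karrikin KAR1, 1 µM of the karrikin KAR2 and 10 µM of rac-GR24, a racemic synthetic strigolactone analogue. KAR2 lacks a methyl group that KAR1 carries. Per the labels, seedlings in liquid medium were treated in parallel within a replicate, and shoots were dissected from whole seedlings after the treatment.

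The authors deposited 17 tables of pairwise comparisons and 1 matrix. The read counts in the tables the authors deposited are whole numbers for total gene reads, total exon reads and total intron reads. The RPKM values that the authors deposited are exon reads scaled by exon length and library size, and all 1363536 values of the matrix equal those in the tables. The p-values that the authors deposited come from an EDGE test of 3 libraries against 3 with tagwise dispersions, given with and without a false discovery correction. The signed fold change that the authors deposited writes a fall by a factor as a negative number. The other per-sample measure, the exon number that the authors deposited, counts the exons of the gene model on which reads were counted. The aligner and the genome build are not given in the sources used here. Coordinates below are those of the deposited annotation columns, as chromosome, first and last base of the coding sequence.

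Exon numbers of 10690 of 37876 features differed between replicate 3 and replicates 1 and 2, so the authors counted the 12 libraries of replicate 3 on other gene models. Exon reads made up between 80.5% and 81.4% of gene reads in replicates 1 and 2 and between 60.0% and 61.7% in replicate 3. Mean exon reads of 2850 of 13539 genes differed by more than 2-fold between replicate 3 and the others, against 38 of 15266 genes for gene reads. Total gene reads, summed over the features of a gene, were therefore used, which gave 25522 genes. This choice was made after the values were seen. In 1 of the 17 tables, WT against Bdkai2-2 under GR24, the columns of 1 Bdkai2-2 GR24 library hold WT KAR1 replicate 2; counts were taken from the other tables. Depth was between 12369851 gene reads (Bdkai2-2 KAR2 replicate 3) and 22493039 gene reads (Bdkai2-1 KAR1 replicate 2) per library. Reads carry no molecular identifiers, so counting error alone understates the spread; replicate libraries differed by 6.39 to 52.6 times counting error (chi-square per degree of freedom over 36 pairs).

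Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM normalization (factors between 0.945 and 1.064), filterByExpr on the 12 groups, 12 group means over all 36 libraries and quasi-likelihood tests with 24 residual degrees of freedom. The filter kept 19507 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called, and "rose" and "fell" are used of called genes. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Normalised read counts (CPM, after TMM scaling) are given as mean ± SD of n = 3 libraries unless stated otherwise. The interaction tests compare the mean treatment response of both mutants with that of WT. Mutants were also compared with WT in the mock and over the 4 treatments together. Files were read in Python 3.11.15 with pandas 2.3.3. The fit was tested on simulated data in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold in 3 libraries. Of these 41.8%, 73.1% and 98.5% were called, and 14 of all 156 calls were false.

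The numbers pair the samples. Deviations from the group means correlated more between libraries of the same replicate number (median r of 0.168 over 198 pairs, above 0.1 in 130; medians of 0.161, 0.094 and 0.361 for replicates 1, 2 and 3) than between others (median r of -0.095), and in 22 of 66 pairs of groups all 3 values were above 0.1. A fit with the replicate number as a block is given beside a result where it changes a call or moves a count by more than 1.5 times.

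The comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. The rule names every tested member of 3 lists (KAI2 and strigolactone signalling, karrikin response markers, strigolactone biosynthesis). It adds up to 10 rising and 10 falling genes with the largest change per WT treatment and for both mutants together, at 1 CPM or more in the higher group and with no overlap between libraries (for the mutants, the same direction in each treatment). From each list it takes up to 4 called members with the smallest p, and for interactions and compound differences up to 5 genes each way. The text describes the genes that matter most among these. Genes singled out after their values were seen are named as such.

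Lists were matched by annotation text and tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 27 lists in 7 comparisons (189 tests). The other lists are auxin response, auxin transport, ethylene, cytokinin, gibberellin metabolism, abscisic acid and water deficit, jasmonate, B-box and light signalling, light harvesting, circadian clock, glutathione transferases, glycosyltransferases, cytochromes P450, heat shock and chaperones, cell wall expansion, phosphate starvation, flavonoid biosynthesis, defence proteins, class III peroxidases, nitrate and cytosolic ribosomal proteins, with marker lists of root, seed and endosperm, shoot meristem and leaf base, and chloroplast-rich leaf. The text search for karrikin response markers matched 0 genes, so that list could not be tested. A marker annotated in other words would be missed, so this does not show that such genes are absent from the data. Of the 189 tests, 55 passed; 3 of these held with an estimated correlation, 52 with the replicate block. These 3 are the KAI2 and strigolactone signalling list for KAR2 and for GR24 in WT and the glutathione transferases for GR24 in WT. By fry, which tests each list's balance of direction without comparing it with other genes, 51 passed.

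Alternatives planned before were DESeq2 1.42.0 size factors in the same fit, a DESeq2 Wald test, no filter on low counts, the replicate block, fits of the compared groups alone, leaving out each library of the compared groups in turn, and WT libraries split between the mutants. Added after the data were seen were total exon reads, alone and with the block, the 12 libraries of replicate 3 left out, the mean of the ribosomal protein genes as a covariate, low oxygen and sugar starvation lists, and 5 lists without chance matches of the text search. Every count of called genes was set against other splits of the same libraries. The authors' intron reads were not analysed here.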

Results

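Gene expression was measured in shoots of WT, Bdkai2-1 and Bdkai2-2 seedlings after 4 h with acetone (mock), KAR1, KAR2 or GR24, in 3 libraries per group and 36 in all, each holding between 12369851 and 22493039 gene reads. KAI2 is the receptor-like hydrolase through which karrikins, compounds found in smoke, act in plants, D14 is the related strigolactone receptor, and MAX2 is the F-box protein that works with both. KAR1 and KAR2 were given at 1 µM and GR24 at 10 µM, so that a difference between a karrikin and GR24 is also a difference in dose.

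The first question is whether the KAI2 transcript itself differed in the mutant lines. LOC100830594, the 1 gene annotated as KAI2 (probable esterase D14L; chromosome 1, 12829499 to 12832361, 2 coding exons), held between 314 and 1024 gene reads in each library, or between 24.5 and 47.2 CPM. Over the 4 treatments its log2 fold change against WT was 0.08 in Bdkai2-1 (adjusted p = 0.545) and -0.23 in Bdkai2-2 (adjusted p = 0.0234), a call that was kept in 17 of 24 fits without 1 library each and had an adjusted p of 0.0673 without WT mock replicate 1. Its exon reads were 0 in all 12 libraries of replicate 3, where another gene model was used. No mutation was read from these data, since the tables hold counts alone.

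The KAR1 comparison asks which genes of WT shoots respond to this karrikin. KAR1 raised 65 genes and lowered 5, against 0 in the fit of the compared groups alone (2028 genes at an unadjusted p under 0.05, 1830 in the fit of all groups), 0 with exon reads (961; 71 called with the replicate block), 133 in DESeq2 and 526 without replicate 3. HSPRO1 (LOC100833868, named after nematode resistance; chromosome 2, 53753584 to 53754987) rose from 2.67 ± 0.549 to 21.2 ± 16.3 CPM, a log2 fold change of 2.99 (SE 0.45, adjusted p = 0.00116). PATHOGENESIS-RELATED PROTEIN 1 (LOC100845654), a defence protein, rose by a log2 fold change of 1.87 (SE 0.28, adjusted p = 0.00102), and the dormancy-associated protein homolog 3 (LOC100845526, chosen after its values were seen here) by 0.82 (adjusted p = 0.000119). Among the largest rises were those of an ALP1-like protein (LOC100823053, 3.66), the ubiquitin ligase PUB23 (LOC100825125, 3.47), WRKY53 (LOC100822256, 3.06), the auxin-responsive SAUR32 (LOC104583806, 2.86), CBF7, a cold and drought response factor (2.84), the chaperone dnaJ 8 (LOC100838972, 2.72), WRKY24 (LOC100845575, 2.25) and the calcium-binding CML45 (LOC100824015, 2.17). All 5 genes that fell did so by less than 2-fold: LOC100839281 (-0.80), a BOI-related ubiquitin ligase (LOC100824034, -0.72, adjusted p = 0.000969), zinc finger protein 8 (LOC104583870, -0.63), methylsterol monooxygenase 1-2 (LOC100830254, -0.58) and the cytokinin response regulator ORR9 (LOC100830988, -0.56). Without WT KAR1 replicate 1 the count was 5, without WT mock replicates 1, 2 and 3 it was 34, 29 and 9, and without WT KAR1 replicate 3 it was 110. Of 24 named calls, 4 (HSPRO1, LOC100845654, LOC100845526 and LOC100824034) held without any 1 library. Without WT KAR1 replicate 1 the adjusted p of LOC100823053 was 0.668, LOC100825125 0.211, LOC100822256 0.389, LOC104583806 0.248, CBF7 0.794, LOC100838972 0.474, LOC100845575 0.444 and LOC100824015 0.639. Among the falls it was, for LOC100839281 0.224, LOC104583870 0.148 and LOC100830988 0.342, and without WT KAR1 replicate 2 that of LOC100830254 was 0.243. All 70 called genes had no overlap between the 3 KAR1 and 3 mock libraries, as did 14.9% of tested genes, where chance gives 10%.

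Among the lists, LOC100821911 (chromosome 2, 13098578 to 13100249), called D14 below, rose from 0.323 ± 0.0426 to 1.21 ± 0.424 CPM under KAR1 (log2 fold change 1.91, adjusted p = 0.0374) and the MAX2 homolog LOC100835618 from 23.1 ± 1.96 to 40.2 ± 6.66 CPM (0.80, adjusted p = 0.00563). LOC100821911 is 1 of 3 genes annotated as strigolactone esterase D14, beside LOC100825504 and LOC100825861, and these data do not show which of them is the receptor. The name D14 is used for LOC100821911 by its annotation alone and does not mean that this gene is the strigolactone receptor. In WT mock replicate 1 LOC100821911 held 5 gene reads, LOC100825504 25 and LOC100825861 2189. D14 and MAX2 were 2 of 11 tested members of the KAI2 and strigolactone signalling list, with 2 adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.109). Glutathione transferases, enzymes of detoxification, leaned upward (median 0.19, adjusted p = 3.6e-05; adjusted p = 0.0595 with an estimated correlation), with 1 of 51 rising, glutathione S-transferase 4 (LOC100837677, 0.92), and 8 adjusted over the list alone. Genes of ethylene also leaned upward (median 0.21, adjusted p = 0.00422; adjusted p = 0.396 with an estimated correlation), 1 of 23 rising, an ACC synthase (LOC100836412, 1.13), and 8 adjusted over the list alone. Cytosolic ribosomal protein genes were lower as a set (median -0.14 over 185 genes, adjusted p = 5.88e-07; adjusted p = 0.831 with an estimated correlation), none of them called and 0 adjusted over the list alone. The KAR1 changes correlated at -0.75 over 8022 genes with a component that varied within the groups, described below. The leanings of the lists under KAR1 cannot be told apart from it. Without WT KAR1 replicate 1 the adjusted p of D14 (LOC100821911) was 0.276, of MAX2 (LOC100835618) 0.148, of LOC100837677 0.143 and of LOC100836412 0.444.

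KAR2, given to WT at the same dose, raised 183 genes and lowered 46, with 93 changed by more than 2-fold. In the fit of the compared groups alone 131 genes were called, with exon reads 62 (132 with the replicate block), without replicate 3 123 and with the ribosomal covariate 625. D14 (LOC100821911) rose to 7.59 ± 2.03 CPM, a 23-fold change over mock (log2 fold change 4.52, SE 0.38, adjusted p = 6.89e-08). HSPRO1 reached 17.6 ± 1.73 CPM (2.71, SE 0.45, adjusted p = 0.000585), and the F-box protein SKIP25 (LOC100831714) rose from 0.920 ± 0.0931 to 4.95 ± 0.0755 CPM (2.42, SE 0.29, adjusted p = 6.09e-06). LOC100827172, an uncharacterised gene, rose by 3.23 (adjusted p = 2.4e-06), and LOB DOMAIN 42 (LOC100821648), the gibberellin 2-beta-dioxygenase 8 (LOC100844598), whose class of enzymes inactivates gibberellins, and the nitrate regulatory protein LOC100832160 rose by 3.30, 3.24 and 3.25. Among the largest falls were those of an AAA-ATPase (LOC100825790, -1.90), the calcium-binding CML10 (LOC100828629, -1.85), a PEP carboxylase kinase (LOC100838618, -1.82), the basic helix-loop-helix factor APG (LOC100831535, from 28.1 ± 4.33 to 9.57 ± 0.991 CPM; -1.55), CONSTANS-LIKE 2 (LOC100825617, -1.52) and the myb factor P (LOC100838726, -1.3). Without WT KAR2 replicates 1 and 3 the counts were 143 and 123, and without WT mock replicates 1, 2 and 3 they were 147, 145 and 130. The adjusted p of LOC100844598 was 0.131 without WT KAR2 replicate 3, that of LOC100832160 0.144 without WT mock replicate 3 and that of LOC100838618 0.155 without WT mock replicate 2. Of tested genes, 13.9% had no overlap between KAR2 and mock libraries, where chance gives 10%.

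The KAI2 and strigolactone signalling list passed for KAR2 (adjusted p = 0.000947; adjusted p = 0.0271 with an estimated correlation): MAX2 (LOC100835618) rose to 47.9 ± 3.9 CPM (1.05, adjusted p = 2.14e-05) beside D14, 2 of 11 members, 4 adjusted over the list alone. The direction of the test and the mean (0.52) are upward, while the median of the list is -0.09. Jasmonate genes leaned upward without a called member (median 0.16, adjusted p = 0.000162; adjusted p = 0.463 with an estimated correlation; 5 of 33 adjusted over the list alone). In the nitrate list 1 of 15 rose, the nitrate reductase LOC100827784, from 50 ± 14.8 to 141 ± 7.94 CPM (1.49, adjusted p = 8.6e-05), with 1 adjusted over the list alone; the list's adjusted p was 0.00485 (adjusted p = 0.463 with an estimated correlation). Light harvesting genes were slightly lower (median -0.18, adjusted p = 0.000108; adjusted p = 0.578 with an estimated correlation) with 0 of 21 called. HY5 (LOC100839215), a regulator of light responses, fell from 33.1 ± 8.49 to 17.1 ± 2.22 CPM (-0.95, adjusted p = 0.00525), and B-box protein 20 (LOC100829110) rose by 1.3, 2 of 28 members of a list that did not pass (adjusted p = 0.2; 3 adjusted over the list alone). The symbol BBX20 was also a term of the search for karrikin response markers, which did not match the wording of LOC100829110. Without WT mock replicate 2 the adjusted p of HY5 (LOC100839215) was 0.092 and that of LOC100829110 0.202. The KAR2 changes correlated at -0.4 over 8022 genes with a component that varied within the groups, described below. The leanings of the lists under KAR2 were not separated from it.

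**Figure D1:**
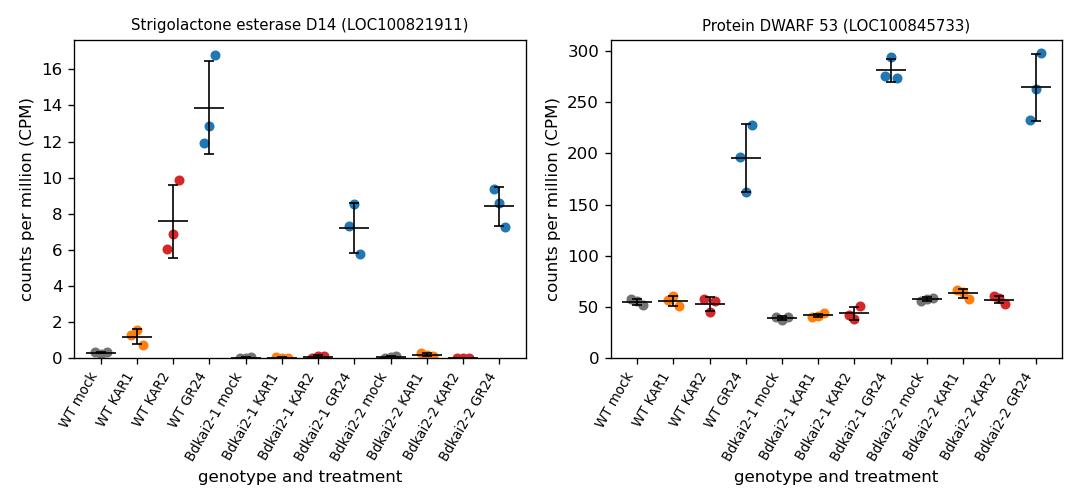
Normalised read counts (CPM) of LOC100821911, annotated as D14, and of DWARF 53 (LOC100845733) in each library by genotype and treatment, with group means and SD. LOC100821911 reached 7.59 CPM with KAR2 and 13.9 CPM with GR24 in WT. DWARF 53 was at 162 CPM or more in the 9 GR24 libraries and at 66.6 CPM or less in the 27 others.

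Both karrikins were compared directly in WT, at the same dose and time. D14 (LOC100821911) was lower under KAR1 than under KAR2 (log2 difference -2.61, SE 0.30, adjusted p = 7.76e-05), as were LOC100845837, an uncharacterised gene (-1.03, adjusted p = 0.00711), a galactinol-sucrose galactosyltransferase (LOC100839679, -1.21, adjusted p = 0.0169), an inositol-tetrakisphosphate 1-kinase (LOC100824952, -0.77) and LOC100834539 (-0.79). The myb factor P (LOC100838726, 1.06, adjusted p = 0.0169), APG (LOC100831535, 0.92) and CONSTANS-LIKE 2 LOC100837783 (0.66) were higher under KAR1. In all, 3 genes were higher and 6 lower under KAR1. Without replicate 3 there were 903 (60.6% higher under KAR1, against 33.3%), and with the ribosomal covariate 48 (8.3%). DESeq2 called 24, and exon reads gave 2, or 46 with the replicate block. In the fit of the compared groups alone there were 0 in edgeR (708 genes at an unadjusted p under 0.05, 796 in the fit of all groups). The 50 genes called for both karrikins rose together in 45 cases and fell together in 5, against 0.6 and 0 if the calls were independent. Both karrikins were set against the same 3 mock libraries: the covariance of the log2 fold changes over all genes was 0.09069, against 0.0557 in 20 simulations of unchanged groups that share the mock (correlation 0.69 against 0.51), and part of the overlap may come from the shared mock. For the 50 genes the median difference was -0.15, and for 40 of the 50 the 95% interval of the difference lay within 1 log2 unit of 0. Among all 229 genes called for KAR2, the change was larger under KAR2 in 219, with a median difference of -0.23 and 108 intervals that exclude 0. Those genes were picked by their KAR2 call, which favours larger KAR2 values. Among the 70 genes called for KAR1 the change was larger under KAR2 in 41 (median difference -0.01), and among the 20 called for KAR1 alone in 0 (median difference 0.70). The count of called differences was 1 without WT KAR1 replicate 2 or 3 or WT KAR2 replicate 2 or 3, 5 without WT KAR2 replicate 1 and 16 without WT KAR1 replicate 1. D14 alone of the 8 named genes held without any 1 library. Without WT KAR1 replicate 2 the adjusted p was 0.26 for LOC100845837, 0.577 for LOC100838726, 0.811 for LOC100831535, 0.88 for LOC100837783 and 0.423 for LOC100839679, LOC100824952 and LOC100834539.

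GR24 at 10 µM raised 688 genes and lowered 346 in WT, 332 of them by more than 2-fold. In the fit of the compared groups alone 281 genes were called (82.6% rising, against 66.5% in the fit of all groups). Exon reads gave 445, or 823 with the replicate block, and the ribosomal covariate gave 1737. Without replicate 3 54.7% of the calls were rising. A 12-oxophytodienoate reductase (LOC100839245; chromosome 1, 3956880 to 3958267), of a family that includes a jasmonate synthesis enzyme, rose from 0.528 ± 0.312 to 34.6 ± 2.42 CPM (log2 fold change 6.01, SE 0.41, adjusted p = 3.04e-11), and D14 (LOC100821911) to 13.9 ± 2.57 CPM (5.39, SE 0.38, adjusted p = 1.41e-10). A quinone oxidoreductase (LOC100833560) rose by 5.06, LOB DOMAIN 42 (LOC100821648) by 4.78, and GSTU6 (LOC100843078) from 20.9 ± 5.19 to 328 ± 81.1 CPM (3.97, adjusted p = 3.93e-12). DWARF 53 (LOC100845733; chromosome 4, 31720907 to 31725497), the repressor that strigolactone signalling degrades, chosen after its values were seen, rose from 55.4 ± 2.86 to 195 ± 32.9 CPM (1.82, SE 0.11, adjusted p = 4.44e-12), against 0.02 under KAR1 and -0.07 under KAR2. The falls included peroxidase N (LOC100827751, -3), ervatamin-B (LOC100839174, -2.84), noroxomaritidine synthase (LOC100822306, -2.25), a PEP carboxylase kinase (LOC100838618, -2.23), CML10 (LOC100828629, -1.89) and HY5 (LOC100839215, -1.77, adjusted p = 3.45e-07). Of tested genes, 17.7% had no overlap between GR24 and mock libraries, where chance gives 10%. Without WT GR24 replicate 3 the count was 562 genes (653 without WT mock replicate 1) and the adjusted p of peroxidase N (LOC100827751) was 0.0717; without WT mock replicate 2 that of ervatamin-B (LOC100839174) was 0.0659.

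Glutathione transferases rose under GR24, 17 of 51 with none falling and 24 adjusted over the list alone (adjusted p = 7.96e-12; adjusted p = 0.00351 with an estimated correlation). Besides GSTU6 they included 2 members annotated as glutathione S-transferase 4 (LOC100837677, 2.76; LOC100827274, 2.44) and LOC100843120 (2.22). The KAI2 and strigolactone signalling list rose (adjusted p = 0.000888; adjusted p = 0.0271 with an estimated correlation), with 4 of 11 members called, 5 adjusted over the list alone: MAX2 (LOC100835618, 0.77) and 3 genes annotated as D14 (LOC100821911; LOC100825504, 1.90; LOC100825861, 0.57). In the nitrate list, 4 of 15 rose, 4 adjusted over the list alone: nitrate reductases LOC100827784 (to 248 ± 80.5 CPM; 2.31) and LOC100829419 (0.73), the nitrite reductase LOC100834109 (0.63) and the transporter LOC100841859 (2.12), with an adjusted p of 0.000162 for the list (adjusted p = 0.324 with an estimated correlation). Without WT GR24 replicate 3 the adjusted p of LOC100841859 was 0.196, and without WT mock replicate 3 those of LOC100834109 and LOC100825861 were 0.132 and 0.0527. Glycosyltransferases showed 12 rising and 2 falling of 62, 15 adjusted over the list alone, but the list did not pass (adjusted p = 0.0579); UDP-glycosyltransferase 73C5 (LOC100828694) rose by 3.19. Of the cytokinin genes 4 rose and 2 fell of 29, with 3 of the LOG family of cytokinin-activating enzymes rising (LOC100842974, 1.48; LOC100841130, 0.55; LOC100829394, 1.10), 7 adjusted over the list alone and an adjusted p of 0.933 for the list. Auxin response genes were lower as a set (median -0.20, adjusted p = 0.0341; adjusted p = 0.588 with an estimated correlation), 3 rising and 4 falling of 61, 11 adjusted over the list alone. B-box and light signalling genes were lower as well (median -0.11, adjusted p = 0.0338; adjusted p = 0.651 with an estimated correlation), with HY5 the 1 called member of 28 and 1 adjusted over the list alone.

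The remaining lists did not pass under GR24 in WT. Counts of called members are followed by the list's adjusted p and the number of members adjusted over the list alone. Cytochromes P450 had 6 rising and 4 falling of 97 (adjusted p = 0.817; 16), flavonoid biosynthesis 2 and 2 of 39 (adjusted p = 0.817; 5), heat shock and chaperones 8 and 2 of 108 (adjusted p = 0.208; 16), cell wall expansion 4 and 3 of 43 (adjusted p = 0.87; 10), jasmonate 3 and 2 of 33 (adjusted p = 0.87; 6), ethylene 2 and 1 of 23 (adjusted p = 0.272; 4) and class III peroxidases 3 and 0 of 70 (adjusted p = 0.355; 3). Phosphate starvation had 0 rising and 1 falling of 56 (adjusted p = 0.329; 1), and gibberellin metabolism 0 of 11 called (adjusted p = 0.943; 0). Auxin transport had 1 and 2 of 18 (adjusted p = 0.78; 4), circadian clock 0 of 10 called (adjusted p = 0.223; 4), defence proteins 1 and 0 of 42 (adjusted p = 0.915; 0) and strigolactone biosynthesis 0 of 3 (adjusted p = 0.772; 0). Abscisic acid and water deficit had 3 and 1 of 22 (adjusted p = 0.959; 6) and cytosolic ribosomal proteins 0 of 185 called (adjusted p = 0.796; 0). Light harvesting had 0 of 21 called (adjusted p = 0.628; 0). Among tissue marker lists, root had 1 rising of 9 (adjusted p = 0.211; 1), shoot meristem and leaf base 0 of 58 called (adjusted p = 0.526; 0), seed and endosperm 2 rising and 1 falling of 18 (adjusted p = 0.14; 5) and chloroplast-rich leaf 1 falling of 28 (adjusted p = 0.609; 1).

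GR24 and KAR2 shared 154 rising and 36 falling genes in WT, against 6.5 and 0.8 if independent. They share the WT mock too: the covariance was 0.1007, against 0.0543 in simulations of unchanged groups (correlation 0.66 against 0.49), and for KAR1 and GR24 0.07821 against 0.05392 (correlation 0.49 against 0.5). In all, 41 genes were called for all 3 compounds, each in 1 direction. Against the karrikins, at 10 times the dose, GR24 gave higher DWARF 53 (LOC100845733; log2 difference of KAR1 and KAR2 from GR24 -1.80 and -1.88, adjusted p = 1.57e-11 and 5.64e-12) and GSTU6 (LOC100843078; -3.02 and -3.76). The quinone oxidoreductase LOC100833560 differed by -4.02 and -4.89. There were 577 genes that differed between KAR1 and GR24 (261 higher under KAR1) and 201 between KAR2 and GR24 (38 higher under KAR2). In fits of the compared groups alone these counts were 109 (18.3% higher under KAR1, against 45.2%) and 37 (5.4% higher under KAR2, against 18.9%). With exon reads they were 212 and 98, or 912 and 169 with the replicate block, and without replicate 3 3210 and 123. That for KAR2 was 376 with the ribosomal covariate. The count for KAR1 was 323 without WT KAR1 replicate 1, 344 without WT KAR1 replicate 2 and 370 without WT GR24 replicate 2. That for KAR2 was 106 without WT KAR2 replicate 1, 131 without WT KAR2 replicate 2 and 113 without WT GR24 replicate 3.

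**Figure D2:**
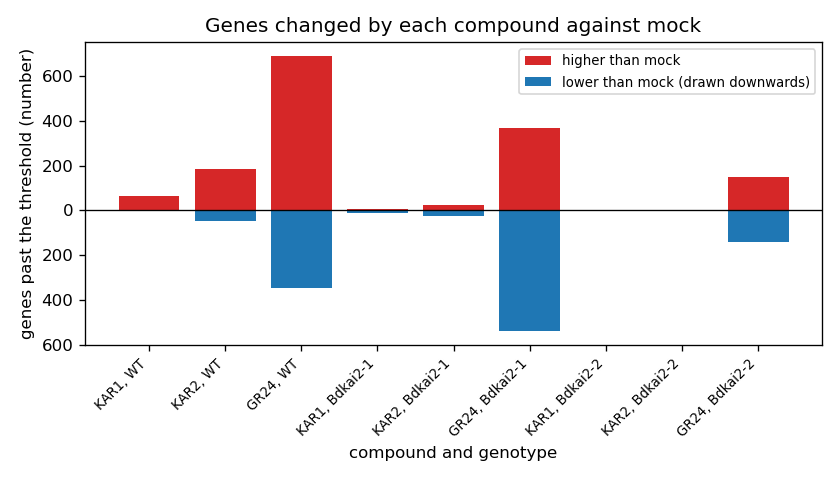
Number of genes called rising and falling for each treatment against the mock in each genotype (3 libraries against 3, all 36 in 1 fit). KAR2 called 229 genes in WT, 50 in Bdkai2-1 and 0 in Bdkai2-2, and without replicate 3 it called 123, 2821 and 2610.

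The mutants were treated to ask which responses need KAI2. In Bdkai2-1, KAR1 raised 7 genes and lowered 10, and KAR2 raised 23 and lowered 27 (34 and 43 with the replicate block). Without replicate 3 these counts were 289 and 2821, in the fit of the compared groups alone 0 (2032 genes at an unadjusted p under 0.05) and 5, and in DESeq2 102 and 120. With the ribosomal covariate they were 51 (66.7% rising, against 41.2%) and 124 (66.9%, against 46%). Exon reads gave 4 (0% rising) and 16 (18.8%), or 60 (43.3%) and 268 (50.4%) with the replicate block. In Bdkai2-2, KAR1 lowered 1 gene, the uncharacterised LOC100821972 (-1.44, SE 0.24, adjusted p = 0.0335, chosen after its values were seen), where 3374 genes had an unadjusted p under 0.05, DESeq2 called 26 and the authors 31. There KAR2 changed 0 genes in edgeR, where 2535 genes had an unadjusted p under 0.05, DESeq2 called 8 and the authors 1. Genes at an unadjusted p under 0.05 for KAR2 numbered 1778 in WT and 1654 in Bdkai2-1. Without replicate 3, KAR1 called 3346 genes and KAR2 2610 in Bdkai2-2, so the order of the genotypes turns. The KAR1 call in Bdkai2-2 was lost in edgeR with exon reads (2142 genes at an unadjusted p under 0.05), the replicate block (3685), the ribosomal covariate (990) and the fit of the compared groups alone (4063). Exon reads with the replicate block gave 308, and 115 for KAR2. With the replicate block KAR1 changed 0 genes there, where 3685 genes had an unadjusted p under 0.05. D14 (LOC100821911) stood at 0.0399 CPM in mock, 0.0355 under KAR1 and 0.0961 under KAR2 in Bdkai2-1, and at 0.0669, 0.212 and 0 CPM in Bdkai2-2. GR24 still raised it in both mutants, to 7.21 ± 1.38 CPM in Bdkai2-1 (adjusted p = 1.52e-10) and 8.42 ± 1.07 CPM in Bdkai2-2 (adjusted p = 3.25e-10), with no fold given because the mocks held almost no reads. In Bdkai2-1 the KAR1 count was 0, 4 and 38 without mock replicates 1, 2 and 3 and 5, 4 and 0 without KAR1 replicates 1, 2 and 3. The KAR2 count there was 12 and 20 without mock replicates 1 and 2 and 13, 29 and 169 without KAR2 replicates 1, 2 and 3. In Bdkai2-2 the adjusted p of LOC100821972 was 0.417 without mock replicate 1. The KAR1 count was 0 without mock replicates 1 or 2 or KAR1 replicates 1 or 2, 3 without mock replicate 3 and 20 without KAR1 replicate 3. The KAR2 count was 1 without KAR2 replicate 2.

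GR24 raised 366 genes and lowered 539 in Bdkai2-1 and raised 147 and lowered 141 in Bdkai2-2. The Bdkai2-1 count was 366 in the fit of the compared groups alone, 384 with exon reads (989 with the replicate block) and 1545 without replicate 3. The Bdkai2-2 count was 97 with exon reads (261 with the replicate block) and 534 with the ribosomal covariate. Of 87 genes called in all 3 genotypes, 83 moved the same way, 64 up and 19 down. DWARF 53 (LOC100845733) rose in both mutants, to 281 ± 11.3 CPM in Bdkai2-1 (2.84) and 264 ± 32.6 CPM in Bdkai2-2 (2.19), a larger response than in WT by 0.69 (adjusted p = 0.00178). GSTU6 (LOC100843078) reached 336 ± 33.2 and 188 ± 7.55 CPM, and the reductase LOC100839245 21.7 ± 2.6 and 12 ± 1.01 CPM. A SMAX1-like gene, LOC100826244, rose by 0.95 and 0.90 (adjusted p = 0.000195 and 0.000771), while its change in WT was 0.41 (adjusted p = 0.133). LOC100825504, also annotated as D14, rose in all 3 genotypes (1.90, 1.83 and 2.18), though its adjusted p was 0.0824 without Bdkai2-1 mock replicate 1 and 0.118 without Bdkai2-2 mock replicate 1. Between WT and Bdkai2-1, 196 shared calls had the same sign (136 up, 60 down) and 112 the opposite. In Bdkai2-1 the GR24 count was 402 without mock replicate 1 and 527 and 543 without GR24 replicates 1 and 3. In Bdkai2-2 it was 131 and 182 without mock replicates 1 and 2 and 154 and 141 without GR24 replicates 2 and 3.

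The response of the mutants was set against that of WT by interaction tests. For KAR2, 157 genes differed, 127 with a lower response in the mutants than in WT and 30 with a higher one. LOC100845837 rose by 1.79 in WT, fell by 1.16 in Bdkai2-1 and had a log2 fold change of 0.35 in Bdkai2-2 (adjusted p = 0.371), an interaction of -2.20 (SE 0.20, adjusted p = 2.24e-07). A probable trehalose phosphate synthase (LOC100821815) and the transcription factor NIGTH1 (LOC100838028) also rose in WT (1.67 and 1.18) and fell in Bdkai2-1 (-0.96 and -0.81), with interactions of -2.01 and -1.47, while APG (LOC100831535) fell in WT (-1.55) and rose in Bdkai2-1 (0.73), an interaction of 1.96. MAX2 (LOC100835618) had interactions of -0.92, -1.32 and -1.36 for KAR1, KAR2 and GR24 (adjusted p = 0.0109, 1.39e-05 and 3.58e-06). D14 (LOC100821911) had a KAR2 interaction of -5.59 (adjusted p = 0.0108), a fitted value that depends on counts of 0 and gives no bound; without Bdkai2-2 mock replicate 3 its adjusted p was 0.12. For KAR1, 32 genes differed (4 with a higher response in the mutants and 28 with a lower one), and for GR24 488 (134 and 354). The KAR1, KAR2 and GR24 counts were 0 (406 genes at an unadjusted p under 0.05, 816 in the fit of gene reads), 42 and 201 with exon reads in edgeR, and 14, 97 and 322 when the replicate block was added. KAR1 gave 49 in DESeq2 and 10 in the fit of the compared groups alone. Without replicate 3 KAR1 and GR24 gave 18 and 274. With the ribosomal covariate KAR2 and GR24 gave 381 and 928. The KAR1 count was 4 without WT KAR1 replicate 1, where the adjusted p of MAX2 (LOC100835618) was 0.149, and 16 and 8 without WT mock replicates 2 and 3. It was 19 without Bdkai2-1 mock replicate 1 or Bdkai2-1 KAR1 replicate 1, 20 without Bdkai2-1 KAR1 replicate 3 or Bdkai2-2 mock replicate 1, and 21 without Bdkai2-2 KAR1 replicate 3. Without WT mock replicate 3 the KAR2 count was 91, and without WT GR24 replicate 3 the GR24 count was 305.

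The last comparison averages the 4 treatments (12 libraries against 12), so responses the mutants lack enter it. Against WT, 1512 genes were higher and 1873 lower in Bdkai2-1, and 1679 and 2112 in Bdkai2-2. In both, 721 were higher and 1038 lower, against 130.1 and 202.8 if independent, and 45 went opposite ways. With exon reads 1694 and 1986 differed in Bdkai2-1 and Bdkai2-2, and 3006 and 3520 with the replicate block. The nitrate reductase LOC100827784 stood at 386 ± 75.4 CPM in Bdkai2-1 and 397 ± 51.5 in Bdkai2-2 (SD, n = 12), against 129 ± 87.4 in WT (log2 fold changes 1.82 and 1.87, SE 0.11 each, adjusted p = 5.98e-13 and 1.27e-13). Universal stress protein PHOS34 (LOC100831945), at 0.0277 ± 0.0524 CPM in WT, stood at 4.78 ± 3.72 and 0.75 ± 1.44 CPM (adjusted p = 2.47e-07 and 0.00826), with no fold given because 2 WT groups held 0 reads. A stearoyl-ACP desaturase (LOC100846588, 5.84 and 2.96), early nodulin-93 (LOC100825538, 5.86 and 2.78), a receptor-like kinase (LOC100828677, 2.46 and 4.85), CYP73A100 (LOC100832881, 6.05 and 2.29) and the protease SBT5.3 (LOC100839099, 2.01 and 2.33) were higher in both. D14 (LOC100821911) was lower, at 1.84 ± 3.29 and 2.17 ± 3.79 against 5.75 ± 5.87 CPM in WT (adjusted p = 2.29e-10 and 3.95e-10). The WT mock held 0.323 CPM, and no fold is given as 1 Bdkai2-2 group held 0 reads. LOC100825504 was lower by log2 values of -1.78 and -2.12. FLOWERING LOCUS T (LOC100823239), which promotes flowering and was chosen after its values were seen, was lower by -2.52 and -3.14, CONSTANS-LIKE 5 (LOC100829198) by -1.54 and -1.42, CML10 (LOC100828629) by -1.53 and -1.60, and the strigolactone synthesis gene D27 (LOC100837900) by -1.10 and -0.75. Without Bdkai2-2 KAR1 replicate 3 the adjusted p of LOC100825538 in Bdkai2-2 was 0.0671.

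Light harvesting genes were lower in both mutants over the 4 treatments, all 15 called members of 21 falling in Bdkai2-2 (median -0.46, 18 adjusted over the list alone, adjusted p = 4.42e-18; adjusted p = 0.16 with an estimated correlation) and 11 in Bdkai2-1 (median -0.15, 12 adjusted over the list alone, adjusted p = 5.88e-05; adjusted p = 0.578 with an estimated correlation). The chloroplast-rich leaf markers moved with them in Bdkai2-2, 9 falling and 1 rising of 28 (median -0.12, 12 adjusted over the list alone, adjusted p = 0.00546; adjusted p = 0.663 with an estimated correlation), while in Bdkai2-1 3 were lower and 1 higher (4 adjusted over the list alone, adjusted p = 0.233). B-box and light signalling genes were lower too, 13 falling and 1 rising of 28 in Bdkai2-2 (adjusted p = 5.49e-07; adjusted p = 0.173 with an estimated correlation; 17 adjusted over the list alone), HY5 (LOC100839215) among them at -1.22. In Bdkai2-1 9 of 28 fell (adjusted p = 0.000693; adjusted p = 0.463 with an estimated correlation; 10 adjusted over the list alone), HY5 at -1.12. Seed and endosperm genes were higher in Bdkai2-1, 9 rising and 1 falling of 18 (adjusted p = 0.000802; adjusted p = 0.0595 with an estimated correlation; 12 adjusted over the list alone), an avenin among them (LOC104583268, 2.55). In Bdkai2-2, glycosyltransferases were lower (20 falling and 2 rising of 62, adjusted p = 0.000131; adjusted p = 0.463 with an estimated correlation; 24 adjusted over the list alone). Cytochromes P450 were lower (31 falling and 9 rising of 97, adjusted p = 0.000269; adjusted p = 0.45 with an estimated correlation; 44 adjusted over the list alone). Jasmonate genes were lower (13 falling and 2 rising of 33, adjusted p = 0.00555; adjusted p = 0.578 with an estimated correlation; 19 adjusted over the list alone). Cytosolic ribosomal proteins were lower in Bdkai2-2 (median -0.19, 14 falling of 185, 0 adjusted over the list alone, adjusted p = 5.52e-07; adjusted p = 0.831 with an estimated correlation). In Bdkai2-1 they were higher (median 0.07, 1 rising, 0 adjusted over the list alone, adjusted p = 0.00477; adjusted p = 0.955 with an estimated correlation). The KAI2 and strigolactone signalling list was lower in both, with 4 of 11 members falling in Bdkai2-1 and 5 falling and 1 rising in Bdkai2-2, 4 and 7 adjusted over the list alone (adjusted p = 0.0338 and 0.0064; adjusted p = 0.171 and 0.0595 with an estimated correlation), D14 and SMAX1-like (LOC100826244, -0.58 and -0.50) among them. MAX2 (LOC100835618) was lower by -0.22 and -0.35 (adjusted p = 0.0726 in Bdkai2-1 without WT KAR1 replicate 1).

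In the mock alone, 728 genes were higher and 529 lower in Bdkai2-1 than in WT, and 376 and 533 in Bdkai2-2. With exon reads 495 and 422 genes differed, and 1306 and 842 when the replicate block was added. For Bdkai2-1 there were 516 in the fit of the compared groups alone and 2082 without replicate 3. For Bdkai2-2 there were 1430 with the ribosomal covariate. The nitrate reductase LOC100827784 stood at 308 ± 21.9 and 411 ± 49.2 CPM, against 50 ± 14.8 CPM in WT (log2 fold changes 2.62 and 3.04), and HY5 (LOC100839215) at 8.2 ± 0.716 and 9.86 ± 0.424 CPM against 33.1 ± 8.49 (-2.01 and -1.75). LOC100845837, which rose with KAR2 in WT, stood at 224 ± 42.8 CPM in the Bdkai2-1 mock and 74.6 ± 5.45 in the Bdkai2-2 mock, against 48 ± 3.31 in the WT mock. MAX2 (LOC100835618), lower on average, was higher by 0.96 in Bdkai2-1. Without Bdkai2-1 mock replicate 1 the count for Bdkai2-1 was 581, and that for Bdkai2-2 was 532 and 473 without WT mock replicates 1 and 2 and 530 and 538 without Bdkai2-2 mock replicates 1 and 2. Without WT mock replicate 1 the adjusted p of LOC100845837 in Bdkai2-2 was 0.094. In the Bdkai2-2 mock 12 of 21 light harvesting genes were lower, 14 adjusted over the list alone (adjusted p = 4.5e-18; adjusted p = 0.16 with an estimated correlation). Chloroplast-rich leaf markers were lower there as well (median -0.19, 2 falling of 28, 5 adjusted over the list alone, adjusted p = 0.00188; adjusted p = 0.622 with an estimated correlation).

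**Figure D3:**
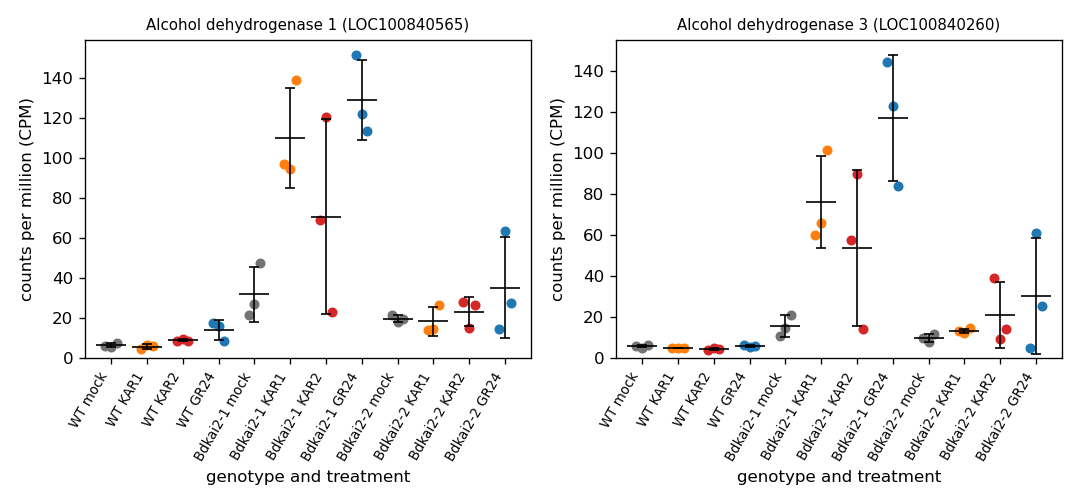
Normalised read counts (CPM) of alcohol dehydrogenase genes LOC100840565 and LOC100840260 in each library by genotype and treatment. ADH1 (LOC100840565) averaged 129 CPM in GR24-treated Bdkai2-1 and 14.2 CPM in GR24-treated WT.

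**Figure D4:**
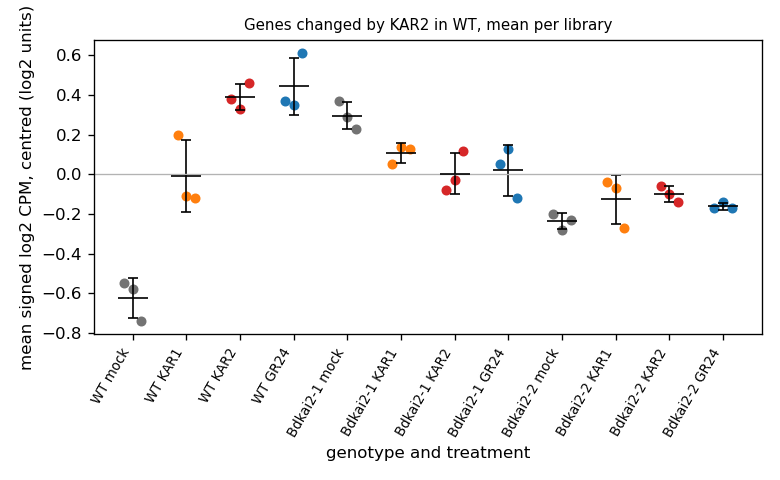
Mean score of the 229 genes called for KAR2 in WT, centred over the 36 libraries and signed by their change in WT, for each library by genotype and treatment. The WT mock averaged -0.62, KAR2-treated WT 0.39, the Bdkai2-1 mock 0.30 and the Bdkai2-2 mock -0.24.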

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

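The results of this part stand out because the response to a compound differed between the mutants and WT by an interaction test. The interaction tests were chosen before the data were examined, while the tests that weigh the 3 patterns at the end were all chosen after the result was seen.

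For KAR1 the response differed in 32 genes. The fitted difference was 1.07 for a BOI-related ubiquitin ligase (LOC100824034), which fell in WT by 0.72 and rose in Bdkai2-1 by 0.57. It was 0.86 for zinc finger protein 8 (LOC104583870), 0.77 for the response regulator ORR9 (LOC100830988) and 1.01 for the transcription factor APG (LOC100831535). It was -1.04 for the dormancy-associated protein homolog 3 (LOC100845526), which rose in WT by 0.82 and fell in Bdkai2-1 by 0.69. It was -0.92 for a nudix hydrolase (LOC100832721) and -1.97, -1.41 and -0.98 for the uncharacterised LOC100824393, LOC100821814 and LOC100828992. None of the 9 was called for KAR1 in Bdkai2-2. Without WT KAR1 replicate 1 the count was 4, and the adjusted p was 0.0937 for LOC100821814 and LOC100828992, 0.159 for LOC100830988, 0.245 for LOC100831535 and 0.0687 for LOC100832721.

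For KAR2 the response differed in 157 genes. The difference was 1.32 for LOC100824034, 1.96 for APG (LOC100831535), 1.16 for LOC104583870, 1.75 for the myb factor P (LOC100838726) and 1.05 for ORR9 (LOC100830988). It was -2.20 for LOC100845837, -1.28 for a CBL-interacting kinase (LOC100828546), -1.44 for the NF-Y subunit B-8 (LOC100834885), -2.01 for a probable trehalose phosphate synthase (LOC100821815) and -1.47 for NIGTH1 (LOC100838028). In each of the 10 the change in Bdkai2-1 had the sign opposite to that in WT, and 8 of the 10 were called there; none was called in Bdkai2-2.

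For GR24 the response differed in 488 genes. GATA factor 21 (LOC100833248, 1.40), myb P (LOC100838726, 2.15), CIPK2 (LOC100830701, 1.13), the F-box protein PP2-A13 (LOC100844177, 1.24) and an AAA-ATPase (LOC100825790, 2.21) fell in WT and rose in Bdkai2-1. LOC100845837 (-2.89), a probable galactosyltransferase (LOC100839679, -3.47), GUCD1 (LOC100824072, -1.32), LOC100826433 (-2.16) and LOC100836957 (-1.84) rose in WT and fell in Bdkai2-1. None of the 10 was called for GR24 in Bdkai2-2, where the log2 fold changes lay between -0.31 and 0.40.

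Counts were set against other splits of the same libraries. Among 100 splits, 8 gave as many genes as the 32 of KAR1, 3 as many as the 157 of KAR2 and 2 as many as the 488 of GR24. The highest other splits gave 827, 750 and 639 genes. These splits exchanged libraries among the 3 genotypes, separately within the mock and within the treatment. Differences between the genotypes can therefore enter the exchanged interaction. The splits cannot weigh chance for an interaction, and chance is not excluded for any of these counts. The highest values for KAR1 and KAR2 are several times the real counts, which may come from this exchange or from a structure of the samples. A first draw of 33 splits gave 3, 2 and 1 (shares of 0.091, 0.061 and 0.03). The number was raised to 100 after that draw had been seen, so the KAR2 share, 0.061 and then 0.03, is no firm exclusion of chance. For the mutants against WT over the 4 treatments, 1 of 100 splits was as large, the real one (3385 and 3791 genes, highest other 2161 and 649), which excludes chance at this number of splits. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone was as large, 1 of 10, with 0 genes in every other split, for KAR1, KAR2 and GR24 in WT (70, 229 and 1034), KAR1 and GR24 in Bdkai2-1 (17 and 905), KAR1 and GR24 in Bdkai2-2 (1 and 288), both mocks (1257 and 909) and KAR2 against GR24 (201). It was also the largest for KAR1 against KAR2 (9, highest other 1) and KAR1 against GR24 (577, highest other 521, when replicate 3 was exchanged). For KAR2 in Bdkai2-1 (50 genes) 2 of 10 were as large, the other with 213 genes when replicate 3 was exchanged. That is several times the real count, which points to a structure of the samples, and the replicate block gave 77. For KAR2 in Bdkai2-2 (0 genes) it was 10 of 10.

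Genes called for KAR2 in WT moved the other way in Bdkai2-1: over the 229 genes the correlation of the KAR2 changes was -0.57 (-0.59 to -0.54 without 1 library each), 24 genes called in both had opposite signs and 1 the same, and the KAR1 and GR24 changes of Bdkai2-1 gave -0.41 and -0.22. All 3 are set against the Bdkai2-1 mock, whose mean score of these genes was 0.30, with 0.10, 0 and 0.02 after KAR1, KAR2 and GR24, and over all genes that mock against WT and KAR2 in WT correlated at 0.52, against 0.51 in simulations of unchanged groups that share the WT mock (covariance 0.08755 against 0.05548). The ribosomal component between flasks, described below, is not excluded. With the ribosomal mean, which only stands in for it, as a covariate the correlation was -0.49. The component itself correlated with the KAR2 changes at -0.4 in WT, 0.57 in Bdkai2-1 and -0.78 in Bdkai2-2, signs that go with the pattern. Loss of KAI2 in both mutants predicted a negative correlation in Bdkai2-2 too, where it was 0.44 (0.21 with the covariate). That test does not decide, since KAR2 called 0 genes in Bdkai2-2 and its changes there followed the component. A single wrong label or 1 exchanged pair of mock and KAR2 in Bdkai2-1 is argued against, since the mock had the higher score in 9 of 9 pairs of libraries (0.23 to 0.37, against -0.08 to 0.12 under KAR2). An exchange of all 3 pairs cannot be told apart, since it would give the same 24 opposite genes. It was predicted to place the libraries labelled mock above, and those labelled KAR2 below, all KAR1 and GR24 libraries of Bdkai2-1 (-0.12 to 0.14). The mock libraries were above them, while those labelled KAR2 were not all below them. The genotype check covers no treatment labels. It placed 36 of 36 libraries, after a first version that placed 25 of 36 (10 of the 11 others in replicate 3) was redesigned, once that was seen. The reason was that the mean of a library's own group lacked its replicate number while the other genotypes' means held it.

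Low oxygen genes were higher in Bdkai2-1 over the 4 treatments, with a median of 0.61 over 11 genes (0.66 with the ribosomal covariate), 6 rising and 1 falling. A few flasks as the cause are argued against, since the mean was higher than in WT in 12 of 12 pairs of the same treatment and replicate number. Root tissue among the shoots cannot be told apart, since the root list had a median of 0.06 with 5 of 9 genes above 0 (-0.02 over 7 genes without chance matches), none above 0.19 and LOC100836776 and LOC100839927, named after the Casparian strip, at -0.19 and -0.23, values that go against it, but genes such as LOC100844574 (193 CPM in WT) are weak markers of a small share of root. Loss of KAI2 in both mutants cannot be told apart either: the median in Bdkai2-2 was 0.22, higher in 11 of 12 pairs. Seed batch and plant stock are confounded with genotype and stay open.

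Within the groups 1 component held 48.1% of the variance of the deviations over 8022 genes, after the means of the replicate numbers were taken out too. The median r was 0.89 for the ribosomal list and -0.68 for the sugar starvation list (added after the data were seen). With the KAR1 and KAR2 changes r was -0.75 and -0.40 in WT, -0.89 and -0.78 in Bdkai2-2 and 0.64 and 0.57 in Bdkai2-1. GR24 gave -0.31 in WT, 0.5 in Bdkai2-1 and -0.07 in Bdkai2-2. The mocks of Bdkai2-1 and Bdkai2-2 against the WT mock gave -0.56 and 0.09, and these mutants over the 4 treatments 0.03 and 0.01. The gene models of replicate 3 are argued against as 1 shift common to all groups, since the ribosomal mean of replicate 3 lay below the mean of replicates 1 and 2 in 6 of 12 groups. This count cannot test an effect of replicate 3 that differs by group. Component scores of replicates 1, 2 and 3 were 8, 12.5 and -20.4 in GR24-treated WT and -6.7, -6.8 and 13.5 in KAR1-treated WT. In KAR1-treated Bdkai2-1, where replicate 3 did not stand apart, they were 6.7, -3.7 and -3.1. More leaf base in the dissected shoots cannot be told apart, since 6 relations of the ribosomal mean over the 36 libraries differ: r was 0.25 with the chloroplast-rich leaf mean (rho 0.09, permutation p = 0.23, adjusted p = 0.28, 0.18 without the 2 farthest libraries, -0.25 in replicates 1 and 2) and 0.81 with the meristem and leaf base mean (rho 0.87, permutation p = 1e-05, the smallest 1e+05 permutations can give, adjusted p = 6e-05, 0.81 without the 2 farthest, 0.57 in replicates 1 and 2). Against more leaf base go the light harvesting mean (r of 0.47, rho 0.36, permutation p = 0.025, adjusted p = 0.038, 0.39 without the 2 farthest, 0.26 in replicates 1 and 2) and the plastid reads (r of 0.57, rho 0.45, permutation p = 0.011, adjusted p = 0.022, 0.42 without the 2 farthest, 0.4 in replicates 1 and 2), while r with log2 gene reads was 0.19 (rho 0.04, permutation p = 0.44, adjusted p = 0.44, 0.16 without the 2 farthest, -0.04 in replicates 1 and 2). Carbon supply of the flasks cannot be told apart, since sugar was not measured: r with the sugar starvation mean was -0.75 (rho -0.71, permutation p = 0.00049, adjusted p = 0.0015, -0.68 without the 2 farthest, -0.56 in replicates 1 and 2).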

How the results depend on the processing

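Total exon reads, their fit with the replicate block, the replicate 3 omission and the ribosomal covariate were chosen after the data were seen. Of 653 values of 306 named genes, 628 kept direction and side of the threshold under DESeq2 size factors, the DESeq2 Wald test, no filter and the replicate block. Over these 4, exon reads, the replicate 3 omission and the ribosomal covariate together, 4058 values were the same, 445 lost and 3 gained a call, and 7 reversed, none of them called. The losses were uneven: with exon reads 337 values lost their call and 265 were the same. With replicate 3 left out 71 lost their call and 579 were the same. Single genes were not counted in the fits of the compared groups alone or of exon reads with the block. The cause of the changes below was not tested, except that fits of fewer libraries have fewer residual degrees of freedom. With the DESeq2 Wald test the counts were 133 for KAR1 in WT, 102 and 120 for KAR1 and KAR2 in Bdkai2-1, 26 and 8 in Bdkai2-2, 49 for the KAR1 interaction and 24 for KAR1 against KAR2. Without a filter KAR1 in Bdkai2-2 gave 3; with the replicate block it gave 0 (3685 unadjusted) and KAR2 in Bdkai2-1 gave 77. In edgeR fits of only the compared groups KAR1, KAR2 and GR24 gave 0 (2028 genes at an unadjusted p under 0.05), 131 and 281 in WT, 0 (2032 unadjusted), 5 and 366 in Bdkai2-1 and 0 (4063 unadjusted) for KAR1 in Bdkai2-2. The Bdkai2-1 mock gave 516, the KAR1 interaction 10, and the compound differences 0 (KAR1 and KAR2; 708 unadjusted), 109 (KAR1 and GR24) and 37 (KAR2 and GR24). With total exon reads, which replicate 3 holds on other gene models, KAR1, KAR2 and GR24 gave 0 (961 unadjusted), 62 and 445 in WT and 4, 16 and 384 in Bdkai2-1. KAR1 and GR24 gave 0 (2142 unadjusted) and 97 in Bdkai2-2, the mocks 495 and 422, the mutants over the 4 treatments 1694 and 1986, the interactions 0 (406 unadjusted), 42 and 201 and the compound differences 2, 212 and 98. Exon reads with the block gave 71, 132 and 823 for KAR1, KAR2 and GR24 in WT, 60, 268 and 989 in Bdkai2-1 and 308, 115 and 261 in Bdkai2-2. They gave 1306 and 842 for the mocks, 3006 and 3520 for the mutants over the 4 treatments, 14, 97 and 322 for the interactions and 46, 912 and 169 for the compound differences. With the 12 libraries of replicate 3 left out, KAR1 and KAR2 gave 526 and 123 in WT. KAR1, KAR2 and GR24 gave 289, 2821 and 1545 in Bdkai2-1, and KAR1 and KAR2 gave 3346 and 2610 in Bdkai2-2. The Bdkai2-1 mock gave 2082, the KAR1 and GR24 interactions 18 and 274 and the compound differences 903, 3210 and 123. With the ribosomal covariate KAR2 and GR24 gave 625 and 1737 in WT (all 229 and 1034 genes kept), KAR1 and KAR2 gave 51 and 124 in Bdkai2-1, KAR1 and GR24 gave 0 (990 unadjusted) and 534 in Bdkai2-2. The Bdkai2-2 mock gave 1430, the KAR2 and GR24 interactions 381 and 928, KAR1 against KAR2 48 and KAR2 against GR24 376. The overlap of both mutants was 942 or 885 genes with the WT libraries split between them, against 1061 and 1090 with the same 6 WT libraries for both and 1759 with all 12, and 3 of 55 list calls held with an estimated correlation. The reversed values, log2 fold changes with sign changed, were 0.19 for D27 (LOC100837900) for both KAR1 and KAR2 with exon reads, 0.17 for LOC100837720 for KAR2 with exon reads and without replicate 3, 1.42 for LOC100838396 for KAR2 and 0.06 for LOC100831510 for GR24 without replicate 3, and -0.14 for LOC100838396 for GR24 with the covariate.

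Leaving out 1 library at a time gave between 5 and 110 genes for KAR1, 123 and 235 for KAR2 and 562 and 971 for GR24 in WT. In Bdkai2-1 the ranges were 0 to 38, 12 to 169 and 402 to 1049, and in Bdkai2-2 0 to 20, 0 to 1 and 131 to 204. They were 581 to 1396 and 473 to 813 for the mocks, 2978 to 3478 and 3398 to 4019 over the 4 treatments, 4 to 36, 91 to 197 and 305 to 549 for the interactions, and 1 to 16, 323 to 523 and 106 to 184 for the compound differences. Of 619 named calls 460 held without any 1 library and 0 changed sign. What depth limits was not tested, since no simulation varied it; at the depth of these libraries 41.8% of simulated 1.5-fold changes in 3 libraries were called.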

Other observations

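The low oxygen and sugar starvation lists and the low oxygen genes of this part were chosen after the data were seen, while the simulations of shared WT libraries were planned. The p-values of these 2 lists were adjusted over the 49 tests of the added lists alone. They describe the pattern from which the lists were picked and are no independent test of it. Alcohol dehydrogenase 1 (LOC100840565), an enzyme of fermentation, was higher by log2 values of 3.16 (SE 0.23, adjusted p = 6.24e-11) in Bdkai2-1 and 1.48 (adjusted p = 2.18e-05) in Bdkai2-2 over the 4 treatments, alcohol dehydrogenase 3 (LOC100840260) by 3.27 and 1.66, and plant cysteine oxidase 2 (LOC100842232) by 2.74 and 0.94. Pyruvate decarboxylase 2 (LOC100828933) was higher by 1.5 in Bdkai2-1 (adjusted p = 3.26e-09), with 0.13 in Bdkai2-2 (adjusted p = 0.57), and a hemoglobin (LOC100828385) was lower by -0.80 in Bdkai2-1. Under GR24 in Bdkai2-1, alcohol dehydrogenase 1 (LOC100840565) reached 129 ± 20 CPM from 32.2 ± 13.7 CPM in the mock (2.01, adjusted p = 0.00385), with 110 ± 25 CPM under KAR1 (1.78, adjusted p = 0.0937) and 70.9 ± 48.7 CPM under KAR2 (1.15, adjusted p = 0.382). The low oxygen list passed in Bdkai2-1 (6 rising and 1 falling of 11, 7 adjusted over the list alone, adjusted p = 1.54e-06; adjusted p = 0.0292 with an estimated correlation) and in Bdkai2-2 (6 rising, 6 adjusted over the list alone, adjusted p = 0.00125; adjusted p = 0.135 with an estimated correlation). It also passed for GR24 in WT (2 rising, 2 adjusted over the list alone, adjusted p = 0.00489; adjusted p = 0.148 with an estimated correlation) and in the Bdkai2-1 mock (2 rising, 4 adjusted over the list alone, adjusted p = 0.00459; adjusted p = 0.148 with an estimated correlation).

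Sugar starvation genes were higher with GR24 in WT (median 0.56, 16 of 30 rising, 22 adjusted over the list alone, adjusted p = 3.41e-19; adjusted p = 0.035 with an estimated correlation) and in the Bdkai2-1 mock (median 0.57, 17 rising and 1 falling, 22 adjusted over the list alone, adjusted p = 1.41e-21; adjusted p = 0.0292 with an estimated correlation). KAR2 in WT gave 4 rising, 9 adjusted over the list alone (adjusted p = 9.58e-10; adjusted p = 0.148 with an estimated correlation), and KAR1 2 rising, 6 adjusted over the list alone (adjusted p = 1.59e-05; adjusted p = 0.331 with an estimated correlation). In the Bdkai2-2 mock 10 were higher and 2 lower, 17 adjusted over the list alone (adjusted p = 3.27e-08; adjusted p = 0.185 with an estimated correlation). Over the 4 treatments 17 were higher and 4 lower in Bdkai2-1, 23 adjusted over the list alone (adjusted p = 2.04e-07; adjusted p = 0.213 with an estimated correlation), and 13 higher and 6 lower in Bdkai2-2, 22 adjusted over the list alone (adjusted p = 0.0289; adjusted p = 0.737 with an estimated correlation). In Bdkai2-2 over the 4 treatments the nitrate transporter LOC100841859 was lower by -2.86 (adjusted p = 1.92e-06), a fitted value over groups as low as 0.041 CPM, the opposite of the nitrate reductase LOC100827784 (1.87).

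Lists that leaned upward in WT under KAR1 as well were glycosyltransferases (median 0.17, 0 rising and 0 falling of 62, 0 adjusted over the list alone, adjusted p = 0.00542; adjusted p = 0.578 with an estimated correlation), jasmonate (median 0.15, 0 rising and 0 falling of 33, 0 adjusted over the list alone, adjusted p = 0.008; adjusted p = 0.578 with an estimated correlation), abscisic acid and water deficit (median 0.25, 0 rising and 0 falling of 22, 5 adjusted over the list alone, adjusted p = 0.0231; adjusted p = 0.578 with an estimated correlation), nitrate (median 0.29, 0 rising and 0 falling of 15, 0 adjusted over the list alone, adjusted p = 0.0338; adjusted p = 0.578 with an estimated correlation) and cytochromes P450 (median 0.11, 1 rising and 0 falling of 97, 3 adjusted over the list alone, adjusted p = 0.0341; adjusted p = 0.654 with an estimated correlation). Under KAR1 light harvesting (median -0.14, 0 rising and 0 falling of 21, 0 adjusted over the list alone, adjusted p = 0.0033; adjusted p = 0.718 with an estimated correlation) leaned downward. The KAR1 changes correlated at -0.75 with the component within the groups. The median r with that component was -0.25 for glycosyltransferases, -0.18 for jasmonate and -0.34 for abscisic acid and water deficit. It was -0.5 for nitrate, -0.15 for cytochromes P450 and 0.27 for light harvesting. These leanings under KAR1 cannot be told apart from the component. Under KAR2 ethylene (median 0.23, 2 rising and 1 falling of 23, 4 adjusted over the list alone, adjusted p = 0.00419; adjusted p = 0.396 with an estimated correlation), abscisic acid and water deficit (median 0.27, 2 rising and 0 falling of 22, 7 adjusted over the list alone, adjusted p = 0.0381; adjusted p = 0.616 with an estimated correlation) and glutathione transferases (median 0.11, 0 rising and 0 falling of 51, 0 adjusted over the list alone, adjusted p = 0.0478; adjusted p = 0.463 with an estimated correlation) leaned upward.

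Further planned lists passed over the 4 treatments. In Bdkai2-1 these were auxin response (5 rising and 14 falling of 61, 20 adjusted over the list alone, adjusted p = 0.0211; adjusted p = 0.578 with an estimated correlation), cytochromes P450 (9 and 24 of 97, 40 adjusted over the list alone, adjusted p = 0.0383; adjusted p = 0.654 with an estimated correlation), defence proteins (10 and 2 of 42, 14 adjusted over the list alone, adjusted p = 0.0498; adjusted p = 0.463 with an estimated correlation) and jasmonate (5 and 8 of 33, 16 adjusted over the list alone, adjusted p = 0.0498; adjusted p = 0.729 with an estimated correlation). In Bdkai2-2 they were cytokinin (9 and 3 of 29, 15 adjusted over the list alone, adjusted p = 0.0338; adjusted p = 0.463 with an estimated correlation), glutathione transferases (2 and 10 of 51, 13 adjusted over the list alone, adjusted p = 0.0371; adjusted p = 0.463 with an estimated correlation), circadian clock (0 and 3 of 10, 3 adjusted over the list alone, adjusted p = 0.0371; adjusted p = 0.173 with an estimated correlation), phosphate starvation (7 and 19 of 56, 29 adjusted over the list alone, adjusted p = 0.0371; adjusted p = 0.463 with an estimated correlation) and ethylene (0 and 5 of 23, 7 adjusted over the list alone, adjusted p = 0.0417; adjusted p = 0.525 with an estimated correlation).

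In the Bdkai2-1 mock nitrate (5 rising of 15, 6 adjusted over the list alone, adjusted p = 8.42e-05; adjusted p = 0.27 with an estimated correlation) and seed and endosperm genes (5 rising of 18, 5 adjusted over the list alone, adjusted p = 0.000802; adjusted p = 0.0595 with an estimated correlation) were higher. Auxin response (2 rising and 7 falling of 61, 14 adjusted over the list alone, adjusted p = 0.00792; adjusted p = 0.491 with an estimated correlation), light harvesting (0 of 21 called, 0 adjusted over the list alone, adjusted p = 0.0105; adjusted p = 0.785 with an estimated correlation) and B-box and light signalling (1 and 1 of 28, 3 adjusted over the list alone, adjusted p = 0.0371; adjusted p = 0.654 with an estimated correlation) were lower. In the Bdkai2-2 mock heat shock and chaperones were higher (12 rising and 3 falling of 108, 20 adjusted over the list alone, adjusted p = 0.0025; adjusted p = 0.463 with an estimated correlation). B-box and light signalling (7 falling of 28, 9 adjusted over the list alone, adjusted p = 6.44e-07; adjusted p = 0.173 with an estimated correlation), cytochromes P450 (5 and 14 of 97, 25 adjusted over the list alone, adjusted p = 0.00238; adjusted p = 0.463 with an estimated correlation), phosphate starvation (1 and 5 of 56, 12 adjusted over the list alone, adjusted p = 0.00848; adjusted p = 0.405 with an estimated correlation) and circadian clock (1 and 2 of 10, 4 adjusted over the list alone, adjusted p = 0.0185; adjusted p = 0.134 with an estimated correlation) were lower.

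The shared changes of both mutants were set against the covariance that a common WT group gives: it was 0.06855 over all genes, against 0.01377 in 20 simulations without any mutant effect, and the correlation 0.61 against 0.51. The simulated libraries hold neither the pairing by replicate number nor the component within the groups. They called 0.05 genes per mutant on average, while other splits of the real libraries gave up to 2161 and 649. The simulated values, those for a shared WT mock included, may thus be too low. With the WT libraries split between the mutants, 942 or 885 genes were shared, and with 6 WT libraries used for both, 1061 or 1090. For the authors' own calls, 11 genes for KAR1, 51 for KAR2 and 114 for GR24 in WT, the direction here was the same for all. The same libraries were used, so this is no independent check. Of these calls 11, 37 and 113 were called here too. Genes with 0 exon reads in all libraries of replicate 3, where other gene models were used, made up 9, 32 and 53 of the authors' calls. In Bdkai2-1 the authors called 14, 9 and 101 genes for KAR1, KAR2 and GR24, of which 3, 8 and 92 were called here, and in Bdkai2-2 31, 1 and 54, of which 0, 0 and 38 were called here. In the mocks they called 131 and 84, of which 130 and 80 were called here. Genes with 0 exon reads in replicate 3 made up 8, 5 and 38 of the authors' calls in Bdkai2-1, 15, 1 and 27 in Bdkai2-2 and 59 and 35 in the mocks.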
